A study of Mus musculus with 24 samples.

How the data were processed

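RNA was measured in 24 libraries of C2C12 cells, an immortalised mouse myoblast line that can fuse into myotubes. The cells carried a lentiviral vector from which doxycycline, a tetracycline antibiotic, induces uncoupling protein 1 (UCP1). Per the labels' protocols, doxycycline or an equal volume of water was given 24 h after seeding, treatments began 24 h later and RNA was taken at 16 h of treatment. The treatments were 51 µM bovine serum albumin (BSA), 300 µM oleic acid (OA), and 1 µM oligomycin with 300 µM oleic acid (OOA). No BSA level is given for the groups with oleic acid, in either arm. Water and doxycycline arms (Dox_BSA, Dox_OA and Dox_OOA) made 6 groups of 4 libraries, taken from the sample titles. Libraries were made with a NEBNext Ultra II RNA kit, per the labels' protocols, and whether counting used strand is not given in the sources used here.

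The deposited values were FPKM, fragment counts scaled by gene length and library size, which the authors had computed for 56748 Ensembl genes, per the file headers. The submitters' processing notes name STAR, HISAT2, HTSeq, DESeq2, edgeR and STAR-Fusion and the builds GRCm39 and mm39, without versions or the role of each. Multiplied by the gene length in the same file, every value came within 0.01 of a whole number of reads once divided by the value of a single read in its library. This gave 20370651 to 29410667 reads per library. The library size behind the values was a scaled one, a few percent from the read total. Every column of per-sample values was matched to a sample. Coordinates are those of the deposited file. The reference annotation provided with the work follows another mouse build and was not used here.

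Log2(FPKM + 1) values were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend and robust estimation). Genes with an FPKM of at least 1 in at least 4 libraries were kept, which left 12904 genes, 10907 of them protein-coding. A single fit held a mean for each of the 6 groups, with 18 residual degrees of freedom, and 9 contrasts were taken from it: 7 differences between groups and 2 interactions, which compare the oligomycin response, or the oleic acid response, between the arms. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and each is given with its standard error (SE) from that fit. Ucp1 was also tested alone with a two-sided exact permutation test over the 70 assignments of 4 against 4 libraries. The labels do not say that libraries of a group came from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical.

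Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes, except where the closing section says otherwise. The 34 lists were written from background knowledge and share some members. Those with at least 5 measured members, 33 in all, were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and adjustment over the lists within each contrast. At the preset correlation camera sets list genes against the other genes, taken as nearly independent. Its p-values then measure spread across genes more than spread between libraries. An estimated correlation was the alternative, and its adjusted p is printed only where a call was lost with it. Counts of changed members are given after adjustment over all genes tested, and beside it adjusted over the list alone. The text may name 41 key genes, of which 38 were tested. It may also name the protein-coding genes with the largest changes among those past the threshold whose libraries did not overlap between the groups and whose symbol is not a clone or unnamed identifier. Of these there were up to 10 per direction in OA vs BSA, OOA vs OA and Dox_BSA vs BSA, and up to 5 per direction elsewhere, without the overlap condition for the interactions. Up to 4 members of each list with the smallest p complete the rule. Which of these genes and lists the text describes or the closing section counts, 254 gene and 99 list results in all, was chosen after their values were seen. Some of the gene results counted are not described. Results of 3 genes are not reported here, and were left out of the gene results counted and the closing section.

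The procedure was tested on simulated data made from the values of these libraries, with 200 of 12904 genes changed in a simulated OOA vs OA comparison. It called 42% of genes changed 1.25-fold, 68% at 1.5-fold, 82% at 2-fold and 96% at 3-fold, and 4.64% of its calls were false. A simulated OA vs BSA comparison without change gave 0 calls. A slope simulated at 0.5 came out at 0.501 among the 151 genes called in the simulated water arm, a step added after the results were seen. Simulated genes varied independently and 200 were changed, against 7337 called in the real OOA vs OA comparison. These rates and this slope may therefore not carry over to the real data. Replicates of a group were compared before averaging. The smallest chi-square per degree of freedom between a pair was 5.24, over genes with at least 20 reads in the pair, so no pair differed as little as sampling noise allows.

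Alternatives changed the pseudocount to 0.1, removed the filter or raised it to a mean FPKM of 5, rescaled by median-of-ratios factors or to a fixed sum per library (TPM), and fitted only the compared groups. Others dropped robust estimation, used limma-voom on the recovered reads, added the replicate number as a block, or left out each library in turn. A term for replicates 1 and 2 against 3 and 4 was added after the data were seen, because the first component of the residuals parted them outside BSA. For that reason values within these pairs of replicates are given beside pooled ones in the report.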

Results

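Gene expression was measured by RNA sequencing in C2C12 myoblasts with an inducible UCP1, a mitochondrial carrier that lets protons bypass ATP synthase. Cells received water or doxycycline and then BSA, oleic acid, or oligomycin with oleic acid. Oligomycin blocks ATP synthase. Each of the 6 groups held 4 libraries of 20370651 to 29410667 reads, and 12904 genes were tested. The design addresses how blocking ATP synthase and uncoupling the inner membrane alter transcription. No group received doxycycline without the UCP1 vector, so effects of doxycycline and of UCP1 share every comparison between arms. The first principal component of log2 values held 41.6% of the variance. Its mean score was 42.7 ± 1.63 (SD, n = 4) in OOA, 12.6 ± 0.95 in Dox_OOA and below 0 in the other groups.

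Ucp1 (ENSMUSG00000031710, chromosome 8, 84016981 to 84025081, plus strand, GRCm39) checked the labels. It averaged 5.24 ± 0.70 FPKM (SD, n = 4) in BSA, 6.84 ± 0.61 in OA and 4.42 ± 0.67 in OOA. With doxycycline it averaged 336.5 ± 4.08, 322.0 ± 12.4 and 214.9 ± 7.29 FPKM in the same order. The ratios were 64.2, 47.1 and 48.7, and every doxycycline library exceeded every water library (exact permutation p = 0.0286 in each, the smallest that 4 against 4 libraries can give). Under doxycycline, Ucp1 in Dox_OOA was 0.668 of its level in Dox_OA (exact permutation p = 0.0286). The same reads cannot tell the vector's transcript from that of the mouse gene.

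**Figure D1:**
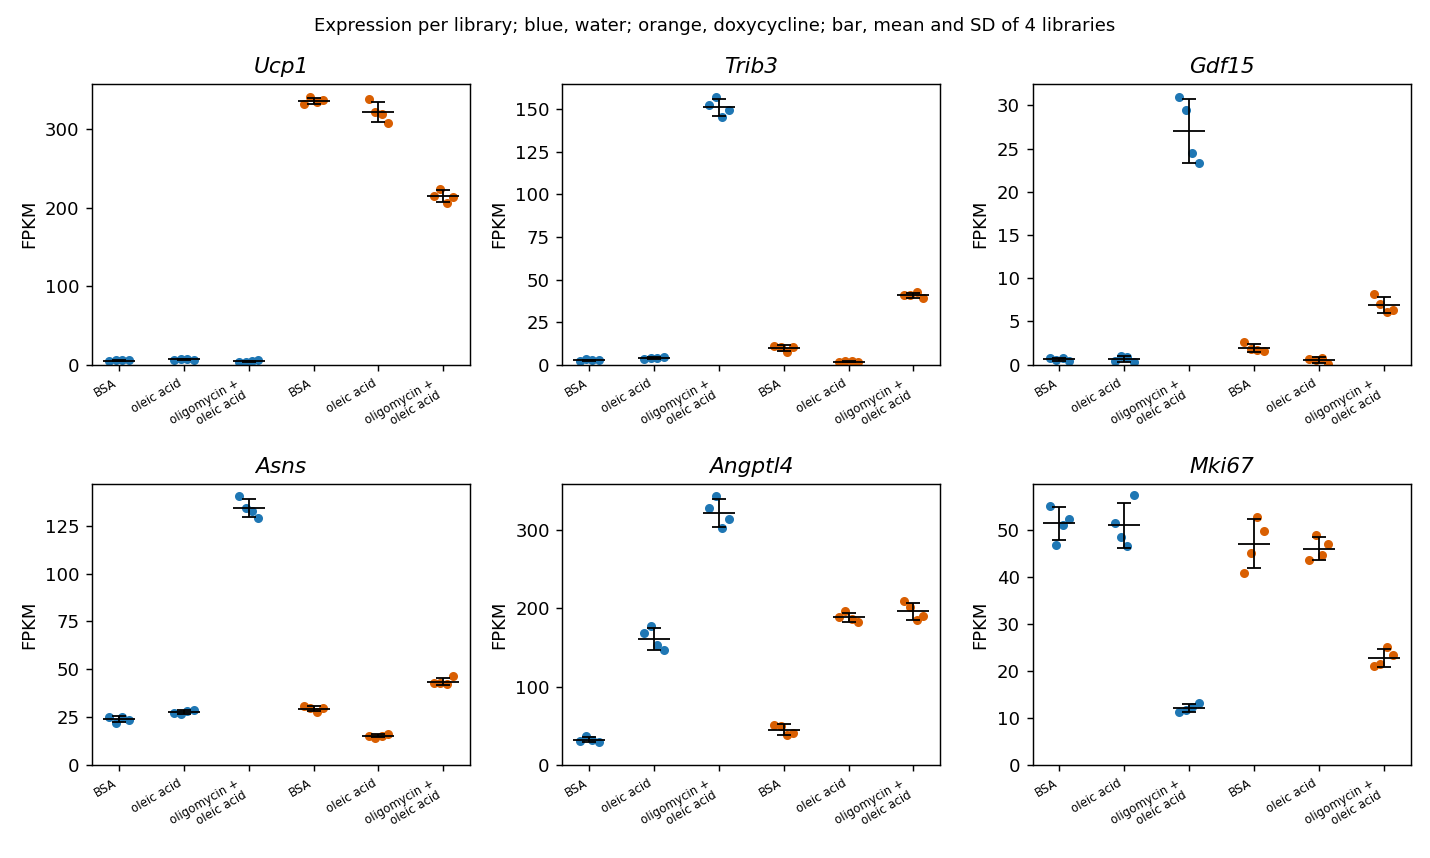
FPKM of 6 genes in each of the 24 libraries (points), with the mean and SD of the 4 libraries of each group (bars); water libraries are blue and doxycycline libraries orange. Trib3 averaged 151.2 FPKM in OOA and 40.8 in Dox_OOA, while Ucp1 was above 206 FPKM in every doxycycline library.

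Oleic acid against BSA in water addressed the response to the fatty acid. The BSA level of the oleic acid groups is not given, so a difference in BSA may share this contrast. Angptl4 (ENSMUSG00000002289, chromosome 17, 33992724 to 34000804), which encodes an inhibitor of lipoprotein lipase, rose from 32.2 ± 3.14 to 161.0 ± 14.0 FPKM (SD, n = 4), a log2 change of 2.29 ± 0.08 (SE). The lipid droplet gene Plin2 rose by 1.13 ± 0.04, the carnitine palmitoyltransferase gene Cpt1a by 0.87 ± 0.03 and Ucp2 by 0.94 ± 0.07. Scd2, a stearoyl-CoA desaturase gene, fell from 306.1 to 107.0 FPKM (log2 change -1.51 ± 0.03, limma adjusted p = 4.57e-19).

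Of 20 measured PPAR targets 9 rose and 11 did not pass (camera adjusted p = 5.91e-13), and 9 rose when adjusted over the list alone. Of 23 beta-oxidation genes 8 rose and 15 did not pass (camera adjusted p = 5.02e-05). Adjusted over the list alone, 9 rose and 1 fell. Several of these genes, Cpt1a and Acaa2 among them, are in the PPAR list too, so the results of these lists are not independent. Acaa2 rose by 0.56 and Acadl by 0.42. Among 25 cholesterol synthesis and SREBP2 genes 17 fell and 8 did not pass (adjusted p = 2.92e-23), with Insig1 at -1.17 and Hmgcs1 at -0.59. Adjusted over the list alone, 20 fell and 1 rose. Of 17 fatty acid synthesis genes 8 fell, or 9 adjusted over the list alone (camera adjusted p = 8.81e-15), among them Srebf1 at -0.74 and Scd1 at -0.60.

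Inflammatory genes rose as well. Of 18 NF-kB and inflammatory genes 14 rose and 4 did not pass, and 16 rose adjusted over the list alone (camera adjusted p = 4.75e-22). They included Il6 (log2 change 1.89 ± 0.17), Saa3 (1.48 ± 0.12), Lcn2 (1.15 ± 0.08) and Cxcl5 (0.92 ± 0.05). The haptoglobin gene Hp rose by 2.11, Stc1 by 2.04, Apln by 1.39, Prl2c2 by 1.09 and Sprr1a by 1.08. The largest falls included the imprinted gene Mest (-1.59 ± 0.09), the carbonic anhydrase genes Car3 (-1.21) and Car2 (-1.09), and Igfbp5 (-0.96).

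Stress response genes were tested too. Of 35 integrated stress response and ATF4 targets 15 rose, or 18 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 1.94e-09). Chac1 rose by 0.57 and Trib3 by 0.45, whereas Ddit3 (0.04 ± 0.07), Atf4 (0.15 ± 0.06) and Fgf21 (-0.18 ± 0.13) did not pass. Of 20 tRNA synthetase genes 10 rose, or 15 adjusted over the list alone (camera adjusted p = 1.94e-09), with Tars at 0.20. Of 18 serine and one-carbon genes 7 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000273). Of 20 glycolysis genes 11 rose, or 12 adjusted over the list alone (camera adjusted p = 1.94e-09, but adjusted p = 0.0519 with an estimated correlation), with Slc16a1 at 0.50 and Ldha at 0.38. The hypoxia-inducible factor list had 7 risen of 20, or 11 adjusted over the list alone (camera adjusted p = 1.93e-07, adjusted p = 0.0728 with an estimated correlation), with Bnip3 at 0.59. Both muscle lists were lower. Of 19 myotube genes 6 fell, or 8 adjusted over the list alone (camera adjusted p = 6.93e-09), such as Chrna1 at -0.56. Of 11 myoblast genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 1.5e-05), such as Myod1 at -0.54. The 36 complex I genes did not pass, singly or as a list (camera adjusted p = 0.559).

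In all, 1070 genes changed, 603 higher and 467 lower, and 20 of them by at least 2-fold. The share of higher calls was 56.4%, and 38.5% with values rescaled to a fixed sum per library. Replicates 1 and 2 alone gave 281 calls, of which 270 had the same sign in replicates 3 and 4, and replicates 3 and 4 alone gave 382, of which 368 had the same sign in 1 and 2.

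Oligomycin with oleic acid against oleic acid in water asked what blocking ATP synthase adds. It moved the largest number of genes of the 9 contrasts, 7337 (3673 higher, 3664 lower), with 744 changed by at least 2-fold. The share of higher calls was 50.1%, and 47.7% with values rescaled to a fixed sum per library. Stress response genes rose and proliferation genes fell. Trib3 (ENSMUSG00000032715, chromosome 2, 152179342 to 152185952), a pseudokinase gene of the stress response, rose from 3.93 ± 0.37 to 151.2 ± 4.97 FPKM (SD, n = 4), a log2 change of 4.95 ± 0.11 (SE). The secreted factor genes Fgf21 and Gdf15 rose by 4.48 ± 0.13 and 4.09 ± 0.16. Mki67, a marker of cycling cells, fell from 50.9 to 12.1 FPKM (log2 change -1.98 ± 0.08, limma adjusted p = 3.58e-16).

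The ATF4 list rose in full, 35 of 35 members over all genes and adjusted over the list alone, with a median of 2.13 (camera adjusted p = 1.99e-31). Atf3 rose by 4.03, Chac1 by 3.59, Aldh1l2 by 3.37, Ddit3 by 3.25, Asns by 2.23 and Atf4 itself by 1.56. Among the 20 tRNA synthetase genes 15 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 7.78e-11), including Wars at 2.10 and Gars at 1.47. Of 18 serine and one-carbon genes, some of them in the ATF4 list, 10 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.00078), with Shmt2 at 1.40. Of 19 p53 targets 17 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 1.96e-09): Sesn2, a member of the ATF4 list too, rose by 2.81, Eda2r by 2.59, Gadd45a by 2.48 and Cdkn1a by 1.17.

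All 25 G2 and M phase genes fell (median -1.72, camera adjusted p = 6.79e-25), and so did all 28 S phase genes (median -1.30, camera adjusted p = 4.2e-20), with the same counts adjusted over the list alone. They included Plk1 (-2.21), Ccna2 (-2.16), Rrm2 (-2.12), Birc5 (-2.01) and Mcm5 (-1.98). Ccnd1, the cyclin D1 gene, fell by 1.46. Of 25 cholesterol genes 18 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 3.61e-05). Of 19 myotube genes 18 fell, also when adjusted over the list alone, with Actc1 at -2.19 and Myh3 at -1.81 (camera adjusted p = 9.21e-07, but adjusted p = 0.108 with an estimated correlation).

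Of 25 complex II to IV genes 19 fell and 2 rose, also when adjusted over the list alone, with Uqcrh at -0.61 (camera adjusted p = 0.00121, but adjusted p = 0.393 with an estimated correlation). Of 16 ATP synthase genes 10 fell, also when adjusted over the list alone (camera adjusted p = 0.00231, but adjusted p = 0.376 with an estimated correlation). The 36 complex I genes had 15 falls and 2 rises, or 12 and 1 adjusted over the list alone, and camera did not pass (adjusted p = 0.0612; 0.0298 without OA replicate 4 and 0.0372 without OOA replicate 2). Of 12 mitochondrially encoded mRNAs 2 fell and 1 rose over all genes, and no member passed adjusted over the list alone (camera adjusted p = 0.792), and mt-Co1 stood at 0.17 ± 0.10 (adjusted p = 0.152, but 0.0276 without OA replicate 4 and 0.0446 without OOA replicate 2). Of 20 glycolysis genes 12 fell and 2 rose, also when adjusted over the list alone, with Ldha at -1.08 (camera adjusted p = 0.000471, but adjusted p = 0.308 with an estimated correlation).

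Other genes rose too. Cdsn, which encodes corneodesmosin of skin, rose from 1.71 to 97.9 FPKM (log2 change 5.19 ± 0.09). The carbonic anhydrase gene Car6 was listed at 0 in all 4 OA libraries and averaged 31.6 FPKM in OOA. Cox6a2 rose by 4.54, Avil by 4.27 and the ATP-gated channel gene P2rx3 by 3.61. Ptgs2, one of the inflammatory list, rose by 3.21. In that list 13 of 18 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.000513, but adjusted p = 0.266 with an estimated correlation). Hmox1 rose by 1.63, Vegfa by 1.58 and Plin2 by 1.41, and Angptl4 rose further by 1.00. Of 20 PPAR targets 9 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.278). Sprr1a (-2.62) and Mxd3 (-2.29) were among the largest falls. Within replicate pairs, 5565 genes were called in replicates 1 and 2 alone, of which 5506 had the same sign in replicates 3 and 4, and 5794 in replicates 3 and 4 alone, of which 5705 had the same sign in 1 and 2.

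Doxycycline against water in BSA asked what inducing UCP1 does without added fatty acid, and changed 281 genes (143 higher, 138 lower). After Ucp1 (5.76 ± 0.07), the largest rises were in Adgrg1 (ENSMUSG00000031785, chromosome 8, 95701379 to 95740845), an adhesion receptor gene, from 1.88 ± 0.13 to 24.3 ± 0.87 FPKM (SD, n = 4; log2 change 3.14 ± 0.05, SE), and in Fam43a (ENSMUSG00000046546, chromosome 16, 30418541 to 30421615), from 8.49 ± 0.86 to 46.2 ± 5.28 FPKM (2.31 ± 0.10). Slc29a3, a nucleoside transporter gene, rose by 1.06 ± 0.06. Stress response genes were also higher: Trib3 rose by 1.57 ± 0.11, Chac1 by 1.06 ± 0.10, Atf3 by 0.88 ± 0.13 and Gdf15 by 0.83 ± 0.16. The Gdf15 call was lost with pseudocount 0.1 (adjusted p = 0.0792) and with limma-voom (0.0641), and that of Atf3 when only the compared groups were fitted (0.0505).

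Of 35 ATF4 targets 17 rose and 18 did not pass, and 24 rose adjusted over the list alone (camera adjusted p = 4.63e-32). Ddit3 rose by 0.46 and Asns by 0.29 (adjusted p = 0.0539 when only the compared groups were fitted), whereas Atf4 (0.05 ± 0.06) and Fgf21 (0.04 ± 0.13) did not pass. Of 20 tRNA synthetase genes 4 rose, or 7 with 2 falls adjusted over the list alone (camera adjusted p = 0.0118, but adjusted p = 0.221 with an estimated correlation, 0.1 without BSA replicate 1 and 0.117 without Dox_BSA replicate 1). Among the 25 cholesterol genes 12 fell, or 19 adjusted over the list alone (camera adjusted p = 2.65e-22), with Insig1 at -0.52 and Sqle at -0.40. Of 20 glycolysis genes 9 fell, or 11 adjusted over the list alone (camera adjusted p = 2.58e-11), with Pgk1 at -0.43 and Ldha at -0.41. The hypoxia-inducible factor list had 6 falls of 20, or 9 adjusted over the list alone, Car9 (-0.84) among them (camera adjusted p = 2.58e-09, but adjusted p = 0.0561 with an estimated correlation).

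Muscle and cell cycle genes were lower. Of 19 myotube genes 4 fell, or 14 adjusted over the list alone (camera adjusted p = 2.91e-09), such as Actc1 (-1.23) and Myh3 (-0.97). Of 25 G2 and M phase genes 5 fell, or 18 adjusted over the list alone (camera adjusted p = 5.24e-15), such as Plk1 (-0.27) and Tpx2 (-0.20), which did not pass when only the compared groups were fitted (adjusted p = 0.118 and 0.113). Hmga2 (-0.74) and Ccnd1 (-0.37) fell, while Mki67 (-0.13 ± 0.08) did not pass. Cdsn (1.04) and Pvalb (0.93) rose. Of 13 interferon-stimulated genes 13 did not pass over all genes and 1 rose adjusted over the list alone, with a camera adjusted p of 0.000905, and Bst2 stood at 0.39 ± 0.11 (adjusted p = 0.0592, and 0.0433 without Dox_BSA replicate 1). The complex I list (camera adjusted p = 0.64) and the PPAR list (adjusted p = 0.687) did not pass. Without BSA replicate 3, BSA replicate 4 or Dox_BSA replicate 2 the count of changed genes was 179, 177 or 173, and it was 80 when only the compared groups were fitted. Replicates 1 and 2 alone gave 54 calls, of which 52 had the same sign in replicates 3 and 4, and replicates 3 and 4 alone gave 90, of which 86 had the same sign in 1 and 2.

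Doxycycline against water in oleic acid asked what inducing UCP1 does with fatty acid added, and changed 1458 genes (553 higher, 905 lower). The share of higher calls was 37.9%, and 55.6% with values rescaled to a fixed sum per library. Adgrg1 rose by 3.29 ± 0.05, Fam43a by 2.29 ± 0.10, Slc29a3 by 0.91 ± 0.06 and Wfdc21 by 0.84 ± 0.15 (SE, n = 4 per group). Amino acid and stress response genes fell: Asns, the asparagine synthetase gene (-0.83), Chac1 (-0.83), Phgdh (-0.81), Trib3 (-0.79), Psat1 (-0.79), Atf5 (-0.62) and Atf4 (-0.51). Ddit3 (-0.08 ± 0.07), Gdf15 (-0.13 ± 0.16) and Plin2 (0.00 ± 0.04) did not pass.

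Among the 35 ATF4 targets 21 fell and 14 did not pass, or 25 fell adjusted over the list alone (camera adjusted p = 8.04e-27). Among the 20 tRNA synthetase genes 17 fell, or 18 adjusted over the list alone (camera adjusted p = 2.34e-23), with Nars at -0.48 and Tars at -0.45. Of 18 serine and one-carbon genes 9 fell and 1 rose, or 12 and 2 adjusted over the list alone (camera adjusted p = 5.68e-10). Of 25 G2 and M phase genes 18 fell, or 22 adjusted over the list alone (camera adjusted p = 7.93e-19), with Plk1 at -0.46 and Tpx2 at -0.33. Of 22 NRF2 targets 5 fell, or 8 adjusted over the list alone (camera adjusted p = 0.000977), Hmox1 at -0.32 and Txnrd1 at -0.29 among them. Of 27 collagen and matrix genes 10 rose and 1 fell, or 11 and 3 adjusted over the list alone, with Col6a1 at 0.24 (camera adjusted p = 3.9e-06, but adjusted p = 0.0686 with an estimated correlation). Of 12 mitochondrially encoded mRNAs 1 rose, also when adjusted over the list alone (camera adjusted p = 0.000585, but adjusted p = 0.332 with an estimated correlation). That gene was mt-Cytb at 0.39 ± 0.10, with an adjusted p of 0.0146, and of 0.0601 without OA replicate 1 and 0.0513 without OA replicate 2. The PPAR list had 2 rises, or 2 and 1 fall adjusted over the list alone, and did not pass (camera adjusted p = 0.262). Without OA replicate 2 the count of changed genes was 963, and it was 935 with no filter on low genes. Within replicate pairs, 300 genes were called in replicates 1 and 2 alone, of which 288 had the same sign in replicates 3 and 4, and 217 in replicates 3 and 4 alone, of which 211 had the same sign in 1 and 2.

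Doxycycline against water in oligomycin with oleic acid asked what inducing UCP1 does while ATP synthase is blocked. Between these groups 5903 genes changed (2843 higher, 3060 lower), 247 of them by at least 2-fold. This contrast also holds doxycycline differences already present in oleic acid alone. Whether the oligomycin response is altered is tested below as an interaction. The share of higher calls was 48.2%, and 56.9% with values rescaled to a fixed sum per library. Stress genes fell and cycling genes rose. Trib3 fell from 151.2 to 40.8 FPKM (log2 change -1.86 ± 0.11, SE, n = 4 per group). Gdf15 (-1.83 ± 0.16), Ddit3 (-1.69 ± 0.07), Fgf21 (-1.64 ± 0.13) and Asns (-1.60 ± 0.05) fell too. Mki67 rose by 0.85 ± 0.08, Ccna2 by 0.97 and Rrm2 by 1.19.

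Of 35 ATF4 targets 35 fell, also when adjusted over the list alone (median -1.35, camera adjusted p = 2.71e-33). Of 20 tRNA synthetase genes 19 fell, also when adjusted over the list alone (camera adjusted p = 7.23e-19), with Wars at -1.63. Of 18 serine and one-carbon genes 13 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 1.75e-07). Of 25 G2 and M phase genes 25 rose, also when adjusted over the list alone (camera adjusted p = 5.5e-19). Of 28 S phase genes 24 rose and 1 fell, or 25 and 1 adjusted over the list alone (camera adjusted p = 1.94e-11). Of 19 p53 targets 17 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 5.29e-10), with Zmat3 at -1.09 and Cdkn1a at -0.90. Of 25 cholesterol genes 16 rose and 1 fell, or 18 and 1 adjusted over the list alone (camera adjusted p = 6.21e-05). Of 18 mitochondrial chaperone and protease genes 14 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 6.21e-05), with Hspa9 at -1.08. Of 12 mitochondrially encoded mRNAs 9 rose, or 10 adjusted over the list alone, with mt-Co2 at 0.94 and mt-Co1 at 0.48 (camera adjusted p = 0.00709, but adjusted p = 0.499 with an estimated correlation). Of 19 myotube genes 13 rose, or 14 adjusted over the list alone (camera adjusted p = 5.65e-05, but adjusted p = 0.136 with an estimated correlation).

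Adgrg1 and Fam43a rose by 2.94 ± 0.05 and 2.84 ± 0.10, Car3 by 2.73, Car2 by 1.63, Myod1 by 0.97 and Ucp2 by 0.91. Falls were seen in Car6 (-2.39), Ptgs2 (-2.32), P2rx3 (-2.27), Cdsn (-2.22), Avil (-2.11), Hmox1 (-1.43) and Plin2 (-0.89). Replicates 1 and 2 alone gave 3903 calls, of which 3827 had the same sign in replicates 3 and 4, and replicates 3 and 4 alone gave 4259, of which 4167 had the same sign in 1 and 2.

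Oleic acid against BSA under doxycycline changed 866 genes (438 higher, 428 lower), 50.6% of them higher, against 42.8% with values rescaled to a fixed sum per library. Angptl4 rose by 2.04 ± 0.08, Hp by 2.03 ± 0.11, Car9 by 1.77 ± 0.07, Il6 and Stc1 by 1.69, Plin2 by 1.19 and Cpt1a by 0.95 (SE, n = 4 per group). Trib3 (-1.92 ± 0.11), Mest (-1.53), Scd2 (-1.41), Chac1 (-1.32), Aldh1l2 (-1.07), Gdf15 (-0.96) and Asns (-0.91) fell. Among the 35 ATF4 targets 28 fell, or 31 with 1 rise adjusted over the list alone (camera adjusted p = 8.76e-46). Among the 20 tRNA synthetase genes 12 fell, or 13 adjusted over the list alone (camera adjusted p = 9.76e-16), with Aars at -0.50. Of 20 PPAR targets 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 9.76e-16). Of 20 glycolysis genes 11 rose, or 14 adjusted over the list alone (camera adjusted p = 6.7e-19), with Ldha at 0.60. Of 18 inflammatory genes 13 rose, or 16 adjusted over the list alone (camera adjusted p = 2.75e-20). Of 17 fatty acid synthesis genes 7 fell, or 8 adjusted over the list alone (camera adjusted p = 5.22e-11). Within replicate pairs, 323 genes were called in replicates 1 and 2 alone, of which 307 had the same sign in replicates 3 and 4, and 455 in replicates 3 and 4 alone, of which 384 had the same sign in 1 and 2. In all 512 genes were called when only the compared groups were fitted.

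Oligomycin with oleic acid against oleic acid under doxycycline changed 4283 genes (2085 higher, 2198 lower). Trib3 rose by 3.88 ± 0.11, Fgf21 by 3.06 ± 0.13, Chac1 by 2.85 ± 0.10, Cdsn by 2.51 ± 0.09, Gdf15 by 2.39 ± 0.16 and Sesn2 by 1.69 (SE, n = 4 per group). Angptl4 (0.06 ± 0.08) did not pass. Sprr1a (-2.05), Sema7a (-1.83), the transferrin receptor gene Tfrc (-1.20), Tnfrsf12a (-1.18), Mki67 (-0.99) and Ccna2 (-0.85) fell. Egr1, an immediate early gene, fell by 1.24 ± 0.40 with an adjusted p of 0.0205, which became 0.0679, 0.0669, 0.0652 and 0.0612 without Dox_OA replicates 1 and 2 and Dox_OOA replicates 3 and 4 in turn. Of 35 ATF4 targets 33 rose, or 34 adjusted over the list alone (camera adjusted p = 1.78e-46). All 25 G2 and M phase genes and all 28 S phase genes fell, also when adjusted over the list alone (camera adjusted p = 1.94e-31 and 8.3e-24). Of 28 lysosome and autophagy genes 22 rose, or 23 adjusted over the list alone (camera adjusted p = 2.84e-10), with Sqstm1 at 0.77 and Ctsl at 0.55. Of 19 p53 targets 9 rose, also when adjusted over the list alone (camera adjusted p = 9.54e-06). Replicates 1 and 2 alone gave 2042 calls, of which 1983 had the same sign in replicates 3 and 4, and replicates 3 and 4 alone gave 2718, of which 2617 had the same sign in 1 and 2.

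The oligomycin response itself differed between the arms, tested as an interaction, in 3834 genes (1950 higher, 1884 lower under doxycycline). Cdsn (-2.69 ± 0.13), P2rx3 (-2.37), Avil (-2.34), Ptgs2 (-2.21), Gdf15 (-1.70 ± 0.23), Ddit3 (-1.61 ± 0.10), Fgf21 (-1.42), Hmox1 (-1.11) and Trib3 (-1.07 ± 0.15) had lower responses under doxycycline (log2, SE, n = 4 per group). That of Gdf15 did not pass with pseudocount 0.1 (adjusted p = 0.0579) or with limma-voom (0.136). Car3 (2.22), Actc1 and Nrep (1.68), Mxd3 (1.52) and Mki67 (1.00) had higher ones. Among the 35 ATF4 targets 33 were lower, or 34 adjusted over the list alone (camera adjusted p = 8.89e-31). All 25 G2 and M phase genes were higher, also when adjusted over the list alone (camera adjusted p = 1.51e-29). Of 28 S phase genes 24 were higher, or 25 adjusted over the list alone (camera adjusted p = 1.31e-17). Of 19 p53 targets 16 were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 1.66e-10). Among the 25 cholesterol genes 15 were higher, or 16 adjusted over the list alone (camera adjusted p = 2.79e-07). Of 19 myotube genes 16 were higher, or 18 adjusted over the list alone (camera adjusted p = 2.68e-08, but adjusted p = 0.0593 with an estimated correlation).

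Among the 7337 genes changed by oligomycin in water, 3536 had a changed response under doxycycline, 3514 of them smaller or of opposite sign and 22 larger, and 6140 kept their sign. Across these genes, which are not independent replicates, the response under doxycycline had a slope of 0.389 on that in water. Choosing genes by their change in water favours smaller responses under doxycycline, both in this slope and in the counts of 3514 and 22. For the 4283 genes chosen in the doxycycline arm, where the choice favours the opposite, the slope of water on doxycycline was 1.498. A further 298 genes with a changed response were not called with oligomycin in water. Of 3673 genes higher with oligomycin in water 1568 were also higher under doxycycline, against 593.5 for independent lists, and of 3664 lower genes 1731 were shared, against 624.1. Within replicate pairs, 1994 genes were called in replicates 1 and 2 alone, of which 1961 had the same sign in replicates 3 and 4, and 2332 in replicates 3 and 4 alone, of which 2264 had the same sign in 1 and 2.

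**Figure D2:**
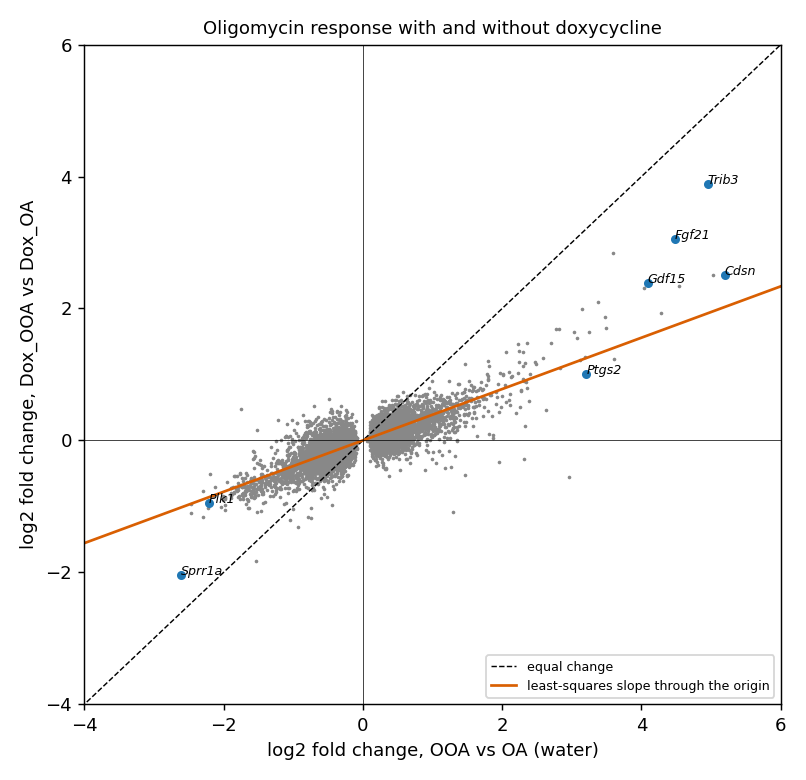
Log2 fold changes with oligomycin in water (horizontal) and under doxycycline (vertical) for the 7337 genes changed in water, each a point, with named genes in blue. The dashed line marks equal change and the orange line is the slope of 0.389, and 1197 genes lie on opposite sides of 0 in the 2 arms.

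The oleic acid response differed between the arms in 82 genes (12 higher, 70 lower under doxycycline). The share of higher calls was 14.6%, and 22.9% with values rescaled to a fixed sum per library. Trib3 (-2.37 ± 0.15), Chac1 (-1.89 ± 0.14), Aldh1l2 (-1.39 ± 0.07), Adm2 (-1.22), Asns (-1.11 ± 0.07), Atf5 (-0.92) and Psat1 (-0.81) had lower responses, and Car9 (1.32 ± 0.10) a higher one (log2, SE, n = 4 per group). Gdf15 (-0.96 ± 0.23, adjusted p = 0.056), Plin2 (0.07 ± 0.06) and Angptl4 (-0.25 ± 0.11) did not pass. Gdf15 was at most 1.0304 FPKM in BSA, OA and Dox_OA. Its interaction did not pass with pseudocount 0.1, limma-voom, no filter, either rescaling, only the compared groups or without robust estimation. Of 16 fits without 1 library, 2 passed: those without OA replicate 4 (adjusted p = 0.0202) and without Dox_OA replicate 3 (0.0333). The adjusted p was 0.0329 among genes with a mean FPKM of at least 5, and 0.00738 with a block for replicate number. A term for replicates 1 and 2 against 3 and 4, added after the data were seen, gave 0.0201. Of 35 ATF4 targets 23 were lower, or 30 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 1.54e-85). Of 20 tRNA synthetase genes 13 were lower, or 16 adjusted over the list alone (camera adjusted p = 2.12e-38). Of 18 serine and one-carbon genes 6 were lower, also when adjusted over the list alone (camera adjusted p = 3.28e-14). Of 25 cholesterol genes 1 was higher, or 4 adjusted over the list alone (camera adjusted p = 3.74e-09). The PPAR list (camera adjusted p = 0.146) had no member past the threshold over all genes, and 1 higher and 1 lower adjusted over the list alone. Replicates 1 and 2 alone gave 29 calls and replicates 3 and 4 alone 22, of which 28 and 22 had the same sign in the other pair, whereas across all genes the interaction had r = -0.00892 between the pairs.

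**Figure D3:**
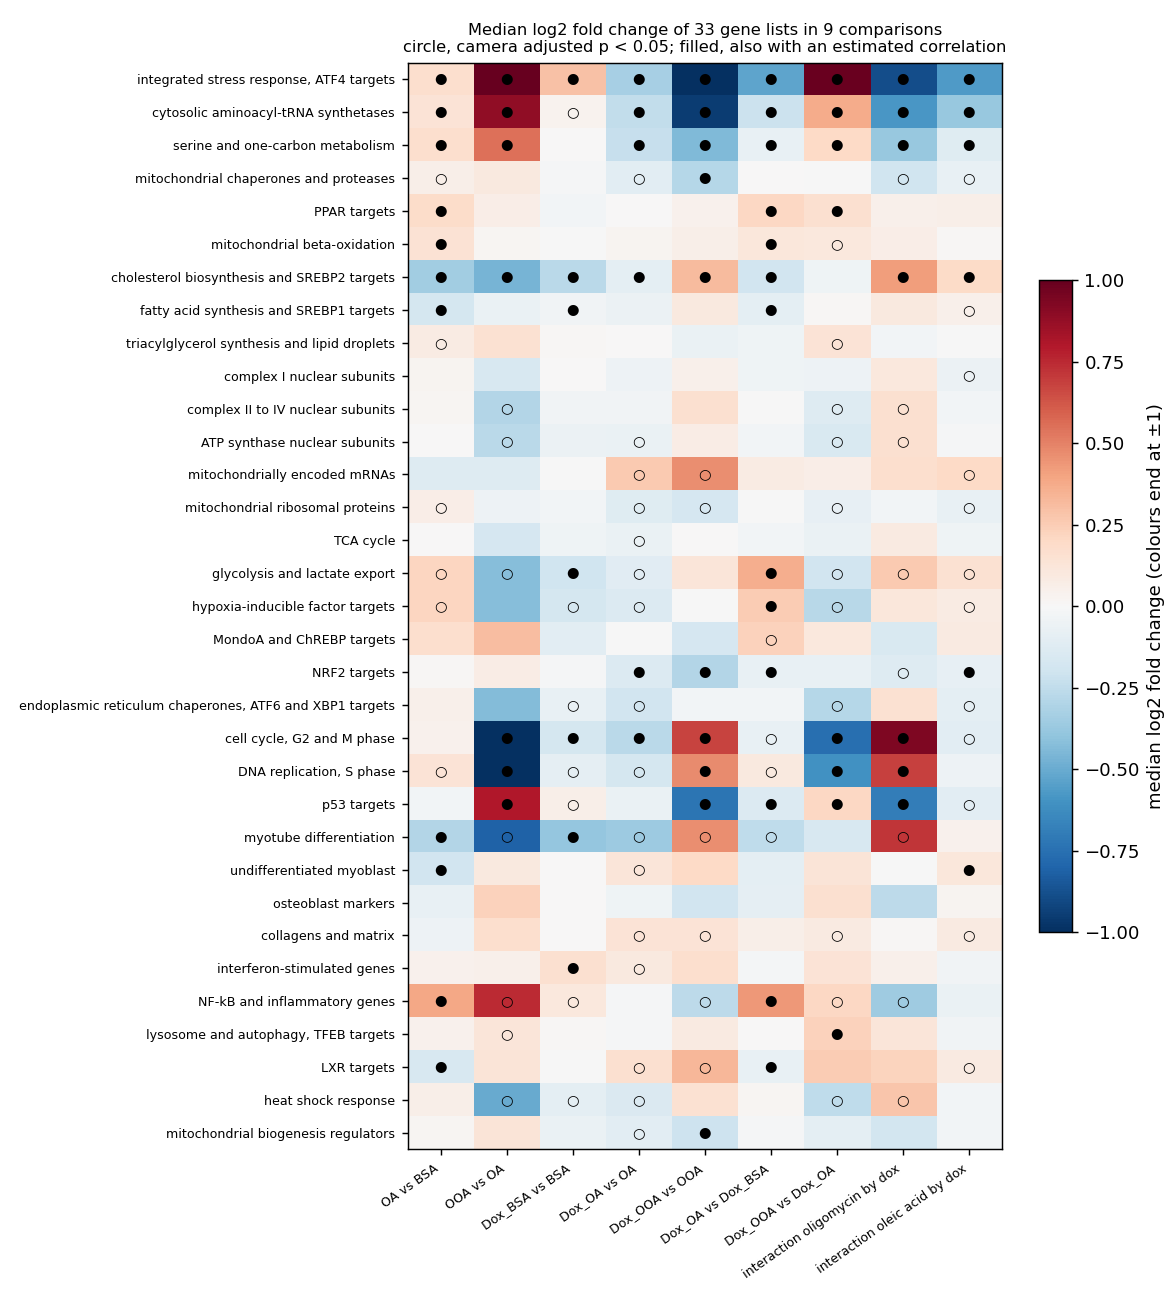
Median log2 fold change (colour) of the 33 tested gene lists, one per line, in the 9 contrasts, one per column. Circles mark lists with a camera adjusted p under 0.05, filled where this also holds with an estimated correlation, as for the ATF4 targets in each of the 9 contrasts.

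Across the 12904 genes, the oligomycin response in water and the doxycycline response in BSA, which share no library, had r = 0.302 (rho = 0.349). Of 143 genes higher with doxycycline in BSA, 113 were also higher with oligomycin in water, against 40.7 for independent lists, and of 138 lower genes 122 were shared, against 39.2. The oleic acid responses in both arms had r = 0.353 (rho = 0.332), which was 0.177 with pseudocount 0.1 and 0.559 among genes with a mean FPKM of at least 5. The doxycycline responses in BSA and in OOA had r = -0.000946 (rho = -0.00796). Of the 143 genes higher with doxycycline in BSA 47 were higher in OOA as well and 71 were lower, against 31.5 and 33.9 for independent lists. These values are across genes, which are not independent replicates, and 3 such correlations were computed.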

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

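The tests on neighbouring genes of Fam43a and Adgrg1 were chosen after their changes were seen, and the neighbours are named outside the rule for naming genes; also chosen after results were seen were the interval of the Gapdh correlation and the condition on pseudogene reads.

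Splitting the libraries in other ways argued against chance as the source of the gene counts of the 7 pairwise comparisons, without excluding it. In each of them 1 of 35 splits, the real one, gave as many genes, the smallest share that 35 splits can give. Splits that mix the groups count a real difference as residual spread, which lowers their counts. Differences between cultures were not tested. The real counts were 1070 (OA vs BSA), 7337 (OOA vs OA), 281 (Dox_BSA vs BSA), 1458 (Dox_OA vs OA), 5903 (Dox_OOA vs OOA), 866 (Dox_OA vs Dox_BSA) and 4283 (Dox_OOA vs Dox_OA), and the highest of the other splits gave 1, 2, 4, 4, 4, 2 and 1 genes in that order. The oligomycin response differed between the arms in 3834 genes by the interaction test, and 3 of 100 splits drawn gave as many, the highest other giving 3967. The oleic acid response differed in 82 genes, and 2 of 100 splits gave as many, the highest other giving 331. The split with 3967 genes exchanged all 8 labels in OOA and 4 in OA, and that with 331 moved 4 in BSA and 0 in OA, so both still held a doxycycline effect of the real libraries. Such splits are not free of change, so signs were also compared between separate libraries. Of the interaction calls made in replicates 1 and 2 alone, 1961 of 1994 (oligomycin) and 28 of 29 (oleic acid) had the same sign in replicates 3 and 4. The other way it was 2264 of 2332 and 22 of 22, so the signs of these genes repeated. Genes can move together and the labels do not say that libraries came from separate cultures, so these counts do not exclude chance.

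The oligomycin response differed between the arms in 29 key genes. Under doxycycline it was lower for Atf4 (-0.7168), Atf5 (-0.6229), Ddit3 (-1.609), Trib3 (-1.071), Asns (-0.7728), Chac1 (-0.7383), Gdf15 (-1.702, but adjusted p = 0.0579 with pseudocount 0.1 and 0.136 with limma-voom), Fgf21 (-1.422), Psat1 (-0.3728), Angptl4 (-0.9376), Plin2 (-0.8889), Hk2 (-0.5373), Vegfa (-1.068), Cdkn1a (-0.8282) and Hmox1 (-1.115). It was higher for Cpt1a (0.5006), Ucp2 (0.6448), Insig1 (0.5296), Fasn (0.2416), Scd1 (0.163), Scd2 (0.6458), Srebf1 (0.4286), Ldha (0.3529), Bnip3 (0.4905), Myod1 (0.7368), Myog (0.7005), Mki67 (0.9964), Ccnd1 (0.392) and Nqo1 (0.3747). The oleic acid response was lower under doxycycline for 7 key genes: Atf4 (-0.5597), Atf5 (-0.9177), Ddit3 (-0.5377, but adjusted p = 0.0519 with limma-voom), Trib3 (-2.367), Asns (-1.115), Chac1 (-1.89) and Psat1 (-0.8064).

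ATF4 targets rose with doxycycline in BSA and fell with it in oleic acid, with a list median of -0.57 for the interaction. After median-of-ratios rescaling, with factors of 0.9923 to 1.009 in these groups, the median was -0.5554. Factors so close together could hardly move the median, so this cannot decide on the deposited scaling as the source. Leaving out each of the 16 libraries gave -0.6071 to -0.5404, and the pairs of replicates gave -0.6866 (1 and 2) and -0.5677 (3 and 4), so neither a single library nor that split carried it. UCP1 activity that depends on fatty acid is a candidate explanation. It cannot be told apart from an effect of doxycycline itself, since 0 libraries received doxycycline without the UCP1 vector.

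Adgrg1 and Fam43a rose with doxycycline in all 3 treatments. Reads shared with Ucp1 are argued against by the changes of both genes between Dox_OA and Dox_OOA. These differed from that of Ucp1 by -0.28 ± 0.09 and 0.78 ± 0.13 (log2, SE), the smaller being 2.996 standard errors. Ucp1 averaged 322.0 FPKM in Dox_OA and 214.9 in Dox_OOA, whereas Fam43a did not fall between them. This limits the vector explanation that follows. Transcription from an inserted vector that reaches neighbouring genes may account for Fam43a: Tmem44, 48.9 kb away, stood at 0.39 (adjusted p = 0.0715), 0.57 and 0.9719 in BSA, OA and OOA, although the nearer Lsg1 (12.1 kb) stood at 0.20, 0.00 and -0.28, and 1042 of the 11726 tested genes with a tested neighbour (8.89%) had one that rose in at least 2 of the 3 doxycycline comparisons. In a wider window of 500 kb, chosen after these values were seen, Atp13a3 at 194 kb stood at 0.10, 0.06 and 0.39, Xxylt1 at 352 kb at 0.72, 0.66 and 1.03 and Acap2 at 490 kb at 0.26, 0.16 and 0.04. For Adgrg1 the neighbour within 100 kb with the largest mean change, Ccdc102a, had 0.04, 0.13 and 0.2264 in BSA, OA and OOA, none of the 19 genes tested within 500 kb rose in at least 2 of the 3, and the tables cannot decide, since the insertion site is not given in the sources used here.

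Gapdh ranged from 130 to 4427 reads over the libraries, and from 263 to 4427 within OA, while Pkm averaged 415.9 and Ldha 318.7 FPKM. Low depth is argued against, since all libraries held 20370651 to 29410667 reads, and those of OA 24005739 to 29410667. These ranges are far narrower than those of Gapdh. A correlation of FPKM values cannot address depth, since FPKM is already scaled by library size. That scaling also removes a loss shared by all genes, so the correlation cannot exclude degraded RNA. The prediction written for degraded RNA was that Gapdh would follow 5 other glycolysis genes (Pgk1, Eno1, Ldha, Pkm and Tpi1). Its within-group deviations had r = -0.3258 with theirs (24 libraries, permutation p = 0.214, rho = -0.3035, permutation p = 0.229), with a 95% interval of -0.6795 to 0.1507, below the bound of 0.3 set before. Without the 2 farthest libraries r was -0.1312 (interval -0.5755 to 0.373), which reaches above that bound, and degraded RNA stays open. A reading that required both intervals was tried first and left degraded RNA open. The reading on 24 libraries was chosen after that was seen. Reads shared with pseudogenes stay open: adding the 3 annotated ones left 99.92% of the variation, but they held 0.0772% of Gapdh reads, which forces that value, and no biological explanation was tested.

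Of 228 groups of 4 libraries tested, 8 held a library far from the other 3, fewer than the 1 in 20 that chance gives. These were reads in OA replicate 1 (29.41 Mreads, others 24.01 to 24.73), Atpif1 in OA replicate 4 (20.63 FPKM, others 23.43 to 23.61), Pdk4 in OOA replicate 1 (36.29, others 29.9 to 30.81) and Myod1 in OOA replicate 4 (24.13, others 25.85 to 26.1). The others were Gdf15 in Dox_BSA replicate 1 (2.586, others 1.613 to 1.772), Srebf1 in Dox_OA replicate 2 (21.35, others 18.19 to 18.31), Asns in Dox_OOA replicate 4 (46.5, others 42.33 to 42.93) and mt-Co1 in Dox_OOA replicate 4 (4689, others 5280 to 5395).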

How the results depend on the processing

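The term for replicates 1 and 2 against 3 and 4 was chosen after the residuals were seen, and all other alternatives before. Direction and status, called or not called, stayed the same under every alternative run for them for 226 of 254 gene results. The same was so for 73 of 99 lists. Some of these gene results are not described above. Counts within 1.5 times the main count were taken as held, which was so for 6 of 9 gene counts and 1 of 9 list counts. None of the slopes and correlations across genes held. The 6 Ucp1 means were judged by a shift below the SD of their group. Leaving out 1 of 4 libraries cannot exceed that, so their holding tests nothing. The 9 gene results and 2 lists that turned direction had no call. Lists were not rerun with TPM rescaling, voom, other filters, only the compared groups or without robust estimation, Ucp1 means were rerun on leaving out libraries only, and some named genes fall below a mean FPKM of 5. Leaving out 1 library gave -0.0116 to 0.0679 (Ddit3), -0.11 to 0.12 (Gdf15) and -0.0711 to 0.0282 (Mki67) in OA vs BSA, and -0.0532 to 0.18 (Fgf21) in Dox_BSA vs BSA. It gave -0.0408 to 0.0283 (Plin2) and -0.25 to 0.0469 (Gdf15) in Dox_OA vs OA, -0.0930 to 0.0282 (Mki67) in Dox_OA vs Dox_BSA, -0.0798 to 0.0439 (Mki67, oleic acid by doxycycline) and -0.0924 to 0.0387 (Ucp1, oligomycin by doxycycline). That Ucp1 interaction was 0.043883 with pseudocount 0.1, 0.036736 after TPM rescaling and 0.052666 with voom, and that of Mki67 0.011673 after TPM rescaling. Leave-one-out adjusted p of lists in OA vs BSA ran from 0.000773 to 0.551 (mitochondrial mRNAs), 0.0215 to 0.367 (G2/M) and 0.018 to 0.0518 (triacylglycerol genes). In OOA vs OA they ran from 0.0298 to 0.0983 (complex I), 0.456 to 1 (mitochondrial mRNAs) and 0.0383 to 0.0854 (TCA cycle). In Dox_BSA vs BSA they were 0.241 to 0.942 (complex I) and 0.0022 to 0.117 (tRNA synthetases), and 0.0166 to 0.31 for NF-kB genes, oleic acid by doxycycline. Gene counts were 173 to 302 (Dox_BSA vs BSA) and 963 to 1250 (Dox_OA vs OA). Without a filter 935 genes changed in Dox_OA vs OA, and with only the compared groups 80 in Dox_BSA vs BSA and 512 in Dox_OA vs Dox_BSA. With pseudocount 0.1 the correlation was 0.2275 between oligomycin and doxycycline responses and 0.1773 between oleic acid responses by arm. At a mean FPKM of at least 5 these were 0.3931 and 0.5594, and 0.01927 between doxycycline responses in BSA and OOA. With genes chosen in the doxycycline arm, the slope of water on doxycycline was 1.498. The main slope of 0.389 is of doxycycline on water, so these slopes are not on the same scale. With an estimated correlation lists changed numbered 11 (OA vs BSA), 7 (OOA vs OA), 7 (Dox_BSA vs BSA), 6 (Dox_OA vs OA), 10 (Dox_OOA vs OOA), 8 (Dox_OOA vs Dox_OA), 7 (oligomycin by doxycycline) and 6 (oleic acid by doxycycline). Adjusted p then was 0.0519 (glycolysis), 0.0728 (hypoxia) and 0.206 (triacylglycerol) in OA vs BSA, and 0.0561 (hypoxia) and 0.221 (tRNA synthetases) in Dox_BSA vs BSA. It was 0.393 (complexes II to IV), 0.308 (glycolysis), 0.108 (myotube), 0.266 (NF-kB), 0.376 (ATP synthase) and 0.153 (heat shock) in OOA vs OA. It was 0.332 (mitochondrial mRNAs) and 0.0686 (collagens) in Dox_OA vs OA, 0.499 (mitochondrial mRNAs), 0.224 (mitochondrial ribosome) and 0.136 (myotube) in Dox_OOA vs OOA, 0.173 (MondoA) in Dox_OA vs Dox_BSA and 0.0593 (myotube) for oligomycin by doxycycline. With a block for replicate number, adjusted p was 0.0622 (triacylglycerol, OA vs BSA), 0.0186 (NF-kB, oleic acid by doxycycline) and 0.0425 (hypoxia, OOA vs OA), and the term for the replicate pairs gave 0.0173 and 0.0468 for the last 2. The labels do not say that the numbers pair the samples, and 9 of 60 same-number residual correlations exceeded 0.1, so no pairing was used. Same-number residuals had a mean r of 0.0397 against -0.0132 for other numbers, and 18 of 24 libraries correlated best with their own number, a hint from the data and not the design. The block moved no gene count by over 1.5 times. With it, Gdf15 for oleic acid by doxycycline (adjusted p = 0.00738) and Angptl4 in Dox_OA vs OA (0.00856) passed, and Angptl4 also did with median-of-ratios (0.0498) and TPM rescaling (0.0222), only the compared groups (0.0361), voom (0.0386) and the term for replicate pairs (0.0076).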

Other observations

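The genes and lists below were picked after their values were seen, from lists fixed before, and the term that parts replicates 1 and 2 from 3 and 4 was chosen after the residuals were seen.

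Chaperone genes moved with oligomycin. In OOA vs OA 11 of 14 heat shock genes fell, also when adjusted over the list alone, with Hspa1b at -1.23 and Dnaja1 at -0.78 (camera adjusted p = 0.000513, but adjusted p = 0.153 with an estimated correlation). Endoplasmic reticulum chaperone genes went both ways: 7 of 19 rose and 10 fell, also when adjusted over the list alone (camera adjusted p = 0.111), with Herpud1 at 1.37, Hspa5 at 0.62, Manf at -1.11 and Hsp90b1 at -0.75. Of 23 TCA cycle genes 12 fell and 5 rose, also when adjusted over the list alone, with Idh2 at -0.78 and Ogdh at -0.48 (camera adjusted p = 0.0612, but 0.0467 without OA replicate 4 and 0.0383 without OOA replicate 1). Among 7 osteoblast markers 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.133), with Runx2 at 0.71 and Spp1 at 0.69. In Dox_OOA vs OOA, 9 of 16 mitochondrial biogenesis regulators fell, or 10 with 1 rise adjusted over the list alone (camera adjusted p = 0.01), with Pprc1 at -0.62 and Twnk at -0.58. Of 71 mitochondrial ribosomal protein genes 29 fell and 2 rose there, also when adjusted over the list alone, with Mrps6 at -0.61 (camera adjusted p = 0.00165, but adjusted p = 0.224 with an estimated correlation).

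With oleic acid in water, 2 of 6 LXR targets fell, or 3 adjusted over the list alone (camera adjusted p = 1.16e-06), and both, Scd1 (-0.60) and Srebf1 (-0.74), are also in the fatty acid synthesis list. Of 20 triacylglycerol and lipid droplet genes 4 rose and 2 fell, or 6 and 4 adjusted over the list alone, with Agpat3 at 0.74 and Dgat2 at 0.45 (camera adjusted p = 0.0297, but adjusted p = 0.206 with an estimated correlation and 0.0518 without BSA replicate 3). The adipocyte list, with 4 measured members, was not tested: in Dox_OOA vs OOA, Car3 (2.73), Cebpa (0.56) and Lipe (0.28) rose and Pparg stood at -0.26.

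The first component of the residuals, 11.6% of their variance, parted replicates 1 and 2 from 3 and 4 outside BSA, a split that the labels do not name. Its largest loadings were in Dox_BSA, 0.495 for replicate 1 and -0.435 for replicate 3. Those of Dox_OA were near 0, from -0.0274 to 0.025. A test of that split on the same residuals restates it, so no p-value is given. Among genes lower in replicates 3 and 4, picked for this text, the mean log2 difference was -0.99 for Egr1, -0.60 for Fos, -0.46 for Ccn1, -0.43 for Ier3, -0.41 for Junb and -0.22 for Bnip3.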
